A study of Mus musculus with 6 samples.

How the data were processed

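RNA was measured in 6 samples from the femurs of 3 male C57BL/6 mice aged 8 weeks that had been given saline by intraperitoneal injection. Per the labels' protocols, each femur was scraped and rubbed to take off muscle and periosteum, the metaphyses were cut away, and the marrow was flushed from the shaft with buffered saline. The flushed cells were pelleted and lysed in Trizol, a phenol-based RNA extraction reagent, and gave the central RNA. Trizol was then run through the emptied shaft, and what it lysed gave the endosteal RNA, that is, RNA from whatever stayed on the inner bone surface. The central cells therefore spent time in suspension before lysis and the endosteal cells did not. Biotin-labelled cRNA was made with a one-cycle kit from 2 micrograms of total RNA and hybridised to Affymetrix mouse arrays, 1 array per sample and 3 arrays per region.

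The values are the authors' deposited probe set signals, a linear intensity for each of 45101 probe sets on each array. The software that summarised the probes and any background step are not given in the sources used here, and the scanner files were not used here. Each of the 6 arrays had the same mean signal after trimming 2% of probe sets at each end, between 499.84 and 499.85, so each array appears to have been scaled by 1 factor. Sorted values differed between arrays, so they had not been quantile normalised. The median signal was 97.2, 104 and 106 on central arrays A, B and C and 127, 131 and 120 on endosteal arrays A, B and C. Between 15.9% and 20.1% of probe sets on an array had a signal below 16. Signals of that size hold little information on level, and the number of arrays limits the precision.

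Probe sets were named through the platform annotation, with gene symbols looked up by gene identifier in a RefSeq table of the GRCm38.p6 assembly. Of the probe sets, 34945 named 1 gene, 932 named several, and 9160 were unnamed here, apart from 64 Affymetrix control probe sets. The look-up found 34741 of the 34945 and changed 0 symbols. Each gene was represented by the probe set with the highest mean signal over the 6 arrays among those that named only that gene, which gave 18193 genes, of which 9010 had more than 1 probe set. Of the genes called below, 301 had another probe set that pointed the other way. No genome build is named for the arrays, so no coordinates are given. Some genes are not reported here.

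The signal was transformed as log2(signal + 16), which understates the change of genes with a low signal. All log2 changes, standard errors and fold values are on that scale, whereas means and SDs of signal are on the linear scale. Endosteal and central arrays were compared with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with region as the only term, two-sided, and Benjamini-Hochberg adjustment over all 18193 genes with a threshold of 0.05. A gene is called higher or lower when it passed that threshold. The study's own comparison, the log2 ratio of the mean endosteal to the mean central signal, was computed as a value with no test.

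Gene lists for 25 cell types, tissues and pathways were fixed from general knowledge before the data were examined, together with the design, the rule for named genes and the alternatives other than those named last below. Each list was tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 25 lists. Camera with an estimated correlation and fry were run as alternatives. Camera compares a list with all other genes, whereas fry asks whether its members move one way on balance. The rule named the 15 genes with the largest increase and the 10 with the largest decrease among called genes whose arrays did not overlap and whose mean in the higher region was above the median of all genes. It further named up to 4 called members of each list in the direction most of them took and up to 2 in the other, and a fixed set of niche, bone, osteoclast and blood cell genes. Other members are named below only to describe a list and were chosen after their values were seen.

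The design gives 3 mice and 6 arrays, and the letters A, B and C recur in both regions, so both regions came from the same animals. That a letter marks 1 mouse is not stated. Deviations of same-letter arrays from their region means correlated at 0.05, 0.04 and 0.01 for A, B and C over all genes, and at 0.26, 0.13 and 0.10 over genes above the median level. The main comparison has no block, after the study's own comparison of averages. Because the animals are shared, the values with the letter as a block are printed where they change the call of a named gene. For the lists, the numbers of members called with the block are given together in the results.

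The procedure was tested on simulated arrays with the real means and spreads of the 18193 genes, in which 200 genes were changed. It recovered 31.3% of genes changed by 1 on the log2 scale, 62.7% of those changed by 2 and 78.8% of those changed by 4, and 8% of its calls were false. With the letter as a block it recovered 0% of the changes of 1 and 2 and 47.0% of the changes of 4. The simulated arrays had no letter effect, and with few changed genes the adjustment over all genes is stricter. These shares therefore need not hold for the real arrays. A shifted list was called in the simulation with both the preset and the estimated correlation, and 0 of 25 unchanged lists were called with the preset one. Simulated genes varied independently and few were changed, so this does not show what an estimated correlation can detect on the real arrays. With 3 arrays per region, an exact permutation test of a single value cannot give p below 0.1.

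The alternatives were the letter as a block, pseudocounts of 1 and 64, quantile normalisation, centring of each array on its median, genes above the median level only, the mean of all probe sets of a gene, every probe set on its own, an intensity trend with a robust prior, a test against a 1.5-fold minimum, unmoderated statistics and leaving out each array. Chosen after the data were seen were the letter as a random block (duplicateCorrelation) and scaling of each array to its poly-A control transcripts. Values were tabulated and drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.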

Results

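The comparison asked how RNA from the inner surface of the femoral shaft, where haematopoietic stem cells (HSCs) are thought to have a niche, differs from RNA of the marrow flushed out of the same shafts. There were 3 endosteal and 3 central arrays from 3 mice. Central arrays correlated with each other at r = 0.971 to 0.973 across genes, endosteal arrays at 0.946 to 0.947, and arrays of different regions at 0.922 to 0.937. The first principal component held 47.7% of the variance. The median SD of a gene between replicate arrays was 0.22 on the log2 scale in central and 0.28 in endosteal RNA. All means below are given with the SD over 3 arrays.

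Endosteal RNA carried higher signals than central RNA for most measured genes of bone matrix (19 of 22 called), extracellular matrix (24 of 35), endothelium (18 of 24) and skeletal muscle (19 of 20), and for 17 of 30 HSC niche factor genes and 9 of 19 osteoclast genes. Of 18 B lymphocyte genes, 5 were called lower, and their median of -0.91 was 0.05 when arrays were scaled to the poly-A controls. Of 25 gene lists, 16 passed with camera at the preset correlation and 0 with an estimated correlation (lowest adjusted p = 0.147; 0.246 for the B cell list). Fry, the other alternative for lists, called 13 higher and 1 lower, the B cell list (fry adjusted p = 0.0398). Of 18193 genes, 1409 were called higher and 723 lower in endosteal RNA by limma. The called increases were larger, with a median log2 change of 1.47 against -0.90 for the decreases, and 988 of the increases but 255 of the decreases reached 2-fold. Of the 1409 increases, 915 (64.9%) had a central mean signal below the median of all genes. The 3 arrays of one region all lay on one side of the other region's for 6822 genes, which is 37.5% of those tested where chance gives 10% for a single gene. Genes share the scale of their array, and the median signal was higher on all endosteal arrays. The 37.5% therefore also holds any shift of scale.

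With the letter shared by arrays of both regions as a block, 85 genes were called higher and 0 lower, while 3026 and 1899 genes had an unadjusted p under 0.05 (3225 and 2060 without the block). In that fit, members called higher were 12 of 20 for skeletal muscle, 10 of 22 for bone matrix and 6 of 35 for extracellular matrix. For osteoclasts, cartilage and TGF-beta and BMP they were 2 of 19, 2 of 15 and 2 of 25. For niche factors and Wnt they were 1 of 30 and 1 of 24. The other lists, among them endothelial, osteocyte, megakaryocyte and B cell genes, had 0 calls. Camera with the block still called 13 lists higher and 3 lower at the preset correlation. With the letter as a random block, chosen after the data were seen, 1668 genes were called higher and 941 lower. That fit ended 0 calls among the 108 named genes, at a consensus correlation of 0.10 between same-letter arrays. Leaving out 1 array gave 608 higher and 152 lower genes without central A, 502 and 89 without central B, 691 and 144 without central C, 741 and 244 without endosteal A, 639 and 202 without endosteal B, and 890 and 297 without endosteal C. Of 108 named genes, the calls that ended were 37, 49 and 28 without central A, B and C and 27, 37 and 26 without endosteal A, B and C. The split depended on scaling and on signal level. Among the 9096 genes above the median level, 1591 were called higher and 1722 lower, so that 48.0% of the calls were higher. Higher genes made up 66.1% of the calls as deposited, 59.6% after quantile normalisation (1085 higher, 734 lower) and 36.8% after centring each array on its median (953 higher, 1638 lower).

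**Figure D1:**
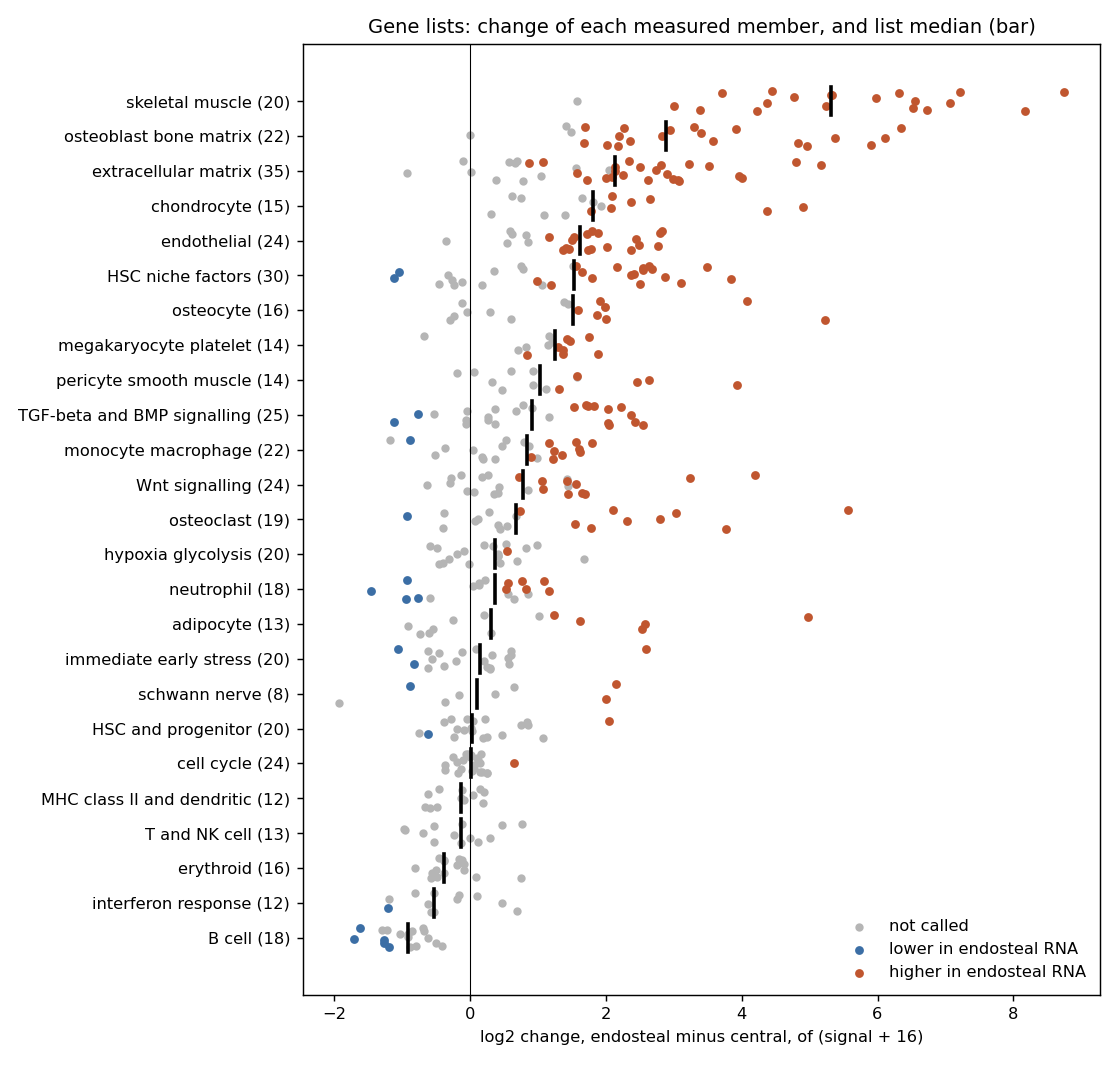
Each point is 1 measured member of a fixed gene list (number of members in parentheses), placed by its log2 change of (signal + 16), endosteal minus central, over 3 arrays per region. Red points were called higher, blue points called lower and grey points neither, and black bars mark list medians, which run from 5.32 for skeletal muscle to -0.91 for B cell genes. When arrays are scaled to the poly-A controls the medians of the B cell, erythroid and interferon lists turn to 0.05, 0.63 and 0.49 and those of the T and NK cell and MHC class II lists turn to 0.74 and 0.77, against 0.96 for all genes. The small medians of the neutrophil, HSC and progenitor, cell cycle, immediate early and Schwann lists turn below 0 under quantile normalisation or median centring.

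Genes of osteoblasts and bone matrix rose together. Of 22 measured members, 19 were called higher and 0 lower (21 and 0 adjusted over the list alone), with a median log2 change of 2.89 (camera adjusted p = 6.21e-18; adjusted p = 0.147 with an estimated correlation). Col1a1 and Col1a2, which encode the chains of type I collagen, the main protein of bone, had signals of 238 ± 68.9 and 527 ± 52.6 in central RNA and 20220 ± 4106 and 37320 ± 3689 in endosteal RNA. Their log2 changes were 6.34 (SE 0.27, adjusted p = 0.00169) and 6.10 (SE 0.14, adjusted p = 0.000417), and both kept their call with the block. Col5a2, a chain of type V collagen, rose by 5.90, and Mmp13, a collagenase made by osteoblasts and hypertrophic chondrocytes, by 5.38. The transcription factor of osteoblast commitment Sp7, at 1.42, did not pass (adjusted p = 0.0663).

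Osteocytes are the cells embedded in bone. Of 16 measured osteocyte genes, 7 were called higher and 0 lower (10 and 0 adjusted over the list alone), with a median of 1.51 (camera adjusted p = 0.000211; adjusted p = 0.163 with an estimated correlation). Dmp1, a mineralisation protein, went from 59.2 ± 25.7 to 2699 ± 521 (log2 change 5.22, SE 0.32, adjusted p = 0.00243). Phex, an endopeptidase of phosphate balance, rose by 4.08 from a signal near background (7.21 ± 9.17), a size that ran from 2.36 to 6.06 over alternatives. The potassium channel gene Kcnk2 rose by 2.01 and the membrane protease gene Mmp14 by 1.99. With the block these 4 genes had adjusted p from 0.0520 to 0.0630. Sost, the osteocyte inhibitor of Wnt signalling, and Fgf23 had signals near background in both regions (29.8 ± 21.2 and 28.1 ± 16.9 for Sost, 38.5 ± 36.1 and 40.8 ± 62.5 for Fgf23), so that a difference was not detectable at this signal.

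Extracellular matrix genes that stood outside the bone matrix list followed, with 24 of 35 called higher and 0 lower (26 and 0 adjusted over the list alone). Their median was 2.13 (camera adjusted p = 8.11e-16, and 0.147 with an estimated correlation). The small proteoglycan genes Lum and Dcn rose by 5.17 and 4.80, Lox, which crosslinks collagen, by 4.01 and Col3a1, the chain of type III collagen, by 3.96. The means of all probe sets of Dcn and Lox changed by 2.52 and 2.54. Lox and Col3a1 had adjusted p of 0.0585 and 0.0535 with the block. Cartilage genes were also higher, 7 of 15 measured and 0 lower (11 and 0 adjusted over the list alone), with a median of 1.80 (camera adjusted p = 7.42e-06; adjusted p = 0.182 with an estimated correlation). Col2a1, the collagen of cartilage, went from 51.9 ± 33.7 to 1341 ± 578 (log2 change 4.38), Col11a1 rose by 4.90 and Comp by 2.36. Chad rose by 2.65 from a signal near background (9.26 ± 1.43), a size that ran from 1.52 to 3.79 over alternatives. Chad and Comp had adjusted p of 0.0697 and 0.0567 with the block. The aggrecan gene Acan, at 1.92, did not pass (adjusted p = 0.0652).

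The largest increases of all were in skeletal muscle genes, which rose on the same endosteal arrays as the bone, matrix and vessel genes. Of 20 measured members, 19 were called higher and 0 lower (20 and 0 adjusted over the list alone), with a median of 5.32 (camera adjusted p = 5.26e-20; adjusted p = 0.163 with an estimated correlation). Myl1, a myosin light chain of fast fibres, went from 24.8 ± 18.6 to 16710 ± 5020, a log2 change of 8.75 (SE 0.40, adjusted p = 0.00169). The central signal is near background, and the change ran from 7.54 to 9.63 over alternatives. Tnnc2, a fast troponin, rose by 8.17, Mb, the oxygen store myoglobin, by 7.21 and Ckm, the muscle creatine kinase, by 7.07. The muscle genes Myh4, Acta1, Tnnt3, Pvalb, Myh1 and Ckmt2 rose by 6.73, 6.55, 6.53, 6.31, 5.98 and 5.58, and the chaperone gene Cryab, which muscle expresses strongly, by 6.43. Of these, Myh1 and Ckmt2 missed the threshold with the block (adjusted p = 0.0521 and 0.0554). The mean of all probe sets gave smaller changes for Mb, Ckm, Myh4 and Cryab, at 3.56, 4.65, 4.10 and 4.02, and each kept its call. Mb and Ckmt2 also had central signals near background (10.9 ± 5.65 and 11.8 ± 6.60), and their changes ran from 3.56 to 8.47 and from 4.17 to 6.78 over alternatives. Tnnc2, Ckm and Cryab were near background in central RNA too (33.2 ± 25.1, 36.2 ± 18.05 and 32.2 ± 45.4). Their changes ran from 7.11 to 8.82, from 4.65 to 7.61 and from 4.02 to 7.69. Cryab did not pass without central array B (adjusted p = 0.0560). The list's median on each endosteal array, relative to the central mean, was 5.92 for A, 5.04 for B and 5.01 for C. Of the list's genes, 3 had a mean central signal above the median of all genes. The remaining gene among the 15 largest increases, Cpe, which encodes carboxypeptidase E, rose by 5.58, and by 3.33 in the mean of its probe sets.

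Osteoclasts, the cells that resorb bone, were represented by 19 measured genes, of which 9 were called higher and 1 lower (10 and 2 adjusted over the list alone), with a median of 0.67 (camera adjusted p = 0.000101; adjusted p = 0.163 with an estimated correlation). Ctsk, the collagen-degrading cathepsin K, went from 236 ± 59.9 to 11750 ± 1717 (log2 change 5.57, SE 0.23, adjusted p = 0.00169), and Acp5, tartrate-resistant acid phosphatase, from 1619 ± 235 to 11330 ± 876 (log2 change 2.80, SE 0.16, adjusted p = 0.00205). Slc9b2, a sodium/proton antiporter, rose by 3.78 and the proton pump subunit Atp6v0d2 by 3.04, with adjusted p of 0.0568 and 0.0535 under the block. Mmp9, which neutrophils also express and which stands in their list too, fell by 0.93 (adjusted p = 0.0241; 0.0894 with the block).

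Of 30 measured HSC niche factor genes, 17 were called higher and 2 lower (21 and 2 adjusted over the list alone), with a median of 1.54 (camera adjusted p = 6.11e-07; adjusted p = 0.163 with an estimated correlation). Cxcl12, the chemokine that retains HSCs in marrow, went from 2711 ± 1008 to 16260 ± 1717 (log2 change 2.64, SE 0.28, adjusted p = 0.00824). Kitl, which encodes stem cell factor, went from 379 ± 111 to 2462 ± 102 (log2 change 2.69, SE 0.23, adjusted p = 0.00485). The adhesion molecule gene Vcam1 rose from 2675 ± 358 to 7926 ± 1119 (log2 change 1.56, SE 0.18, adjusted p = 0.00951), and Cdh2, which encodes N-cadherin, from 108 ± 41.5 to 851 ± 96.5 (log2 change 2.87, SE 0.30, adjusted p = 0.00723). Tnc, a matrix glycoprotein, rose by 3.85, Slit2, a guidance ligand, by 3.50 and the mesenchymal receptor gene Pdgfra by 3.11. The Notch ligand gene Jag1 rose by 1.20 (adjusted p = 0.0236), but the mean of its probe sets changed by 0.40 (adjusted p = 0.303). That mean was 1.49 for Kitl, 2.02 for Slit2 and 1.90 for Pdgfra, which kept their calls. Angpt1, the ligand of Tie2, had signals of 552 ± 143 and 1164 ± 240 and did not pass (log2 change 1.07, SE 0.26, adjusted p = 0.0567), although the mean of its probe sets did (1.34, adjusted p = 0.0369), as did Angpt1 with pseudocount 64 (0.0303), an intensity trend (0.00236), the random block (0.0412) and among genes above the median level (0.00907). These increases stand beside that of the muscle list on the same arrays, with a median of 5.32. With the block, Slit2 kept its call (adjusted p = 0.0478) and the others had adjusted p between 0.0521 and 0.0630.

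Both niche factor genes called lower, Tgfb1 at -1.12 (adjusted p = 0.0128) and Fn1 at -1.04 (adjusted p = 0.0430), encode transforming growth factor beta 1 and fibronectin, and had adjusted p of 0.0613 and 0.0668 with the block. The mean of the probe sets of Fn1 changed by -0.51 (adjusted p = 0.154), and with pseudocount 1 its adjusted p was 0.0578. Genes of HSCs and progenitors themselves did not move as a list. Of 20 measured, 1 was called higher and 1 lower (3 and 1 adjusted over the list alone), with a median of 0.03 and a camera adjusted p of 0.938. The called ones were Fgd5, which endothelial cells also express, at 2.05 (adjusted p = 0.0241), and the transcription factor gene Gata2 at -0.61 (adjusted p = 0.0432), with 0.0797 and 0.123 under the block. Gata2 did not pass by the mean of its probe sets (-0.55, adjusted p = 0.0636) or with pseudocount 1 (adjusted p = 0.0521). Kit, the receptor for stem cell factor, had signals of 751 ± 68.0 and 904 ± 177 (log2 difference 0.25, adjusted p = 0.444).

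**Figure D2:**
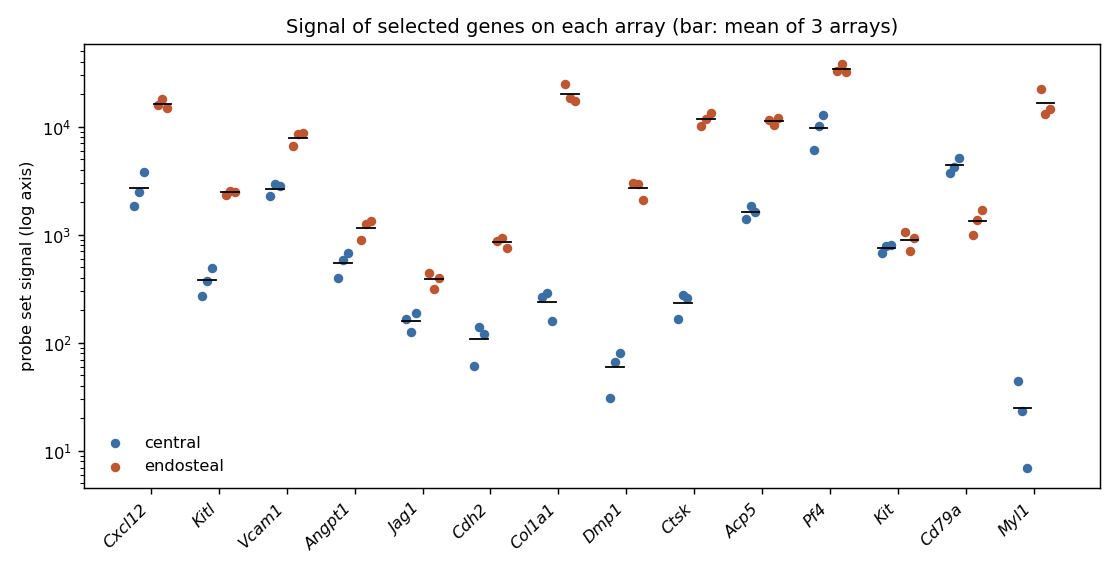
Probe set signal on a log axis for 14 genes, with 3 central (blue) and 3 endosteal (red) arrays each and a bar at each mean. The arrays of the regions do not overlap for 13 of the genes, including Cxcl12 (means 2711 and 16260) and Cd79a (4389 and 1345), and overlap for Kit (751 and 904). Angpt1 did not pass the threshold, and the axis shows that Myl1 (means 24.8 and 16710) spans the widest range.

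Endothelial genes were higher as a group on the arrays that carried the muscle transcripts (muscle median 5.32), with 18 of 24 called higher and 0 lower (23 and 0 adjusted over the list alone) and a median of 1.62 (camera adjusted p = 1.56e-11; adjusted p = 0.163 with an estimated correlation). The transcription factor gene Sox18 rose by 2.83, Clec14a by 2.79, Emcn, which encodes endomucin of sinusoids and veins, by 2.77 and Mmrn2 by 2.49, with adjusted p from 0.0535 to 0.0944 under the block. Clec14a had a central signal near background (22.3 ± 8.43), and its change ran from 1.85 to 3.47 over alternatives. Of 14 pericyte and smooth muscle genes, 5 were called higher and 0 lower (6 and 0 adjusted over the list alone), with a median of 1.03 (camera adjusted p = 0.00110; adjusted p = 0.163 with an estimated correlation). The pericyte gene Rgs5 rose by 3.93, the potassium channel regulator gene Abcc9 by 2.63 and the contractile genes Tagln and Myl9 by 2.46 and 1.57, with adjusted p from 0.0535 to 0.0766 under the block. Tagln had a central signal near background (15.96 ± 9.23), and its change ran from 1.46 to 3.41 over alternatives. Myl9 had an adjusted p of 0.0513 when genes were taken as the mean of their probe sets, 0.0521 after quantile normalisation, 0.0540 after centring and 0.0655 with pseudocount 1, with which Sox18 had 0.0617. Acta2, the smooth muscle actin, did not pass at -0.19 (adjusted p = 0.685).

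Of 13 adipocyte genes, 5 were called higher and 0 lower, whereas 6 were higher and 3 lower when adjusted over the list alone. The list as a whole did not pass (median 0.30, camera adjusted p = 0.327). Car3, a carbonic anhydrase of fat and muscle, rose by 4.98, Adipoq, which encodes adiponectin, by 2.58, the fatty acid carrier gene Fabp4 by 2.53 and the lipase gene Lpl by 1.62, with adjusted p from 0.0615 to 0.0799 under the block. Fabp4 did not pass by the mean of its probe sets (1.91, adjusted p = 0.0823), nor Adipoq with pseudocount 1 (adjusted p = 0.0511). Without central array C the list passed (median 0.70, adjusted p = 0.0411, over alternatives 0.0411 to 0.657). Of 8 Schwann cell and nerve genes, 2 were higher and 1 lower (2 and 2 adjusted over the list alone). S100b rose by 2.15 and Pmp22 by 2.00, while Mbp, which blood cells also transcribe, fell by 0.88, with adjusted p from 0.0535 to 0.0816 under the block. The list's median was 0.10 and its mean 0.23, but camera pointed down (adjusted p = 0.838). The mean of the 8 probe sets of Mbp changed by -0.13 (adjusted p = 0.705).

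Blood cell genes did not move in one direction. Megakaryocyte and platelet genes rose, with 8 of 14 called higher and 0 lower (13 and 1 adjusted over the list alone) and a median of 1.25 (camera adjusted p = 7.42e-06; adjusted p = 0.258 with an estimated correlation). Pf4, the platelet chemokine, went from 9633 ± 3359 to 34290 ± 3174 (log2 change 1.89, SE 0.29, adjusted p = 0.0185). The collagen receptor gene Gp6 rose by 1.75, Rab27b, a GTPase of granule release, by 1.47 and Gp1bb, a subunit of the von Willebrand factor receptor, by 1.43. The mean of the probe sets of Gp1bb changed by 0.71 and did not pass (adjusted p = 0.142). With the block these 4 genes had adjusted p from 0.0697 to 0.0883. Monocyte and macrophage genes were higher too, 9 of 22 with 1 lower (13 and 2 adjusted over the list alone), with a median of 0.83 (camera adjusted p = 0.00110; adjusted p = 0.163 with an estimated correlation). Apoe, the lipid carrier, rose by 1.79, Gpnmb by 1.62, Mrc1, the mannose receptor of resident macrophages, by 1.60 and the complement gene C1qa by 1.56. Ccr2, the chemokine receptor of inflammatory monocytes, fell by 0.88, but by 0.38 in the mean of its probe sets (adjusted p = 0.144). Gpnmb changed by 0.71 in the mean of its probe sets and did not pass either (adjusted p = 0.0640). With the block the 5 genes had adjusted p from 0.0521 to 0.0876.

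Neutrophil genes split, 6 of 18 called higher and 4 lower (9 and 5 adjusted over the list alone), and the list did not pass (median 0.37, camera adjusted p = 0.270). The genes of early granulocyte precursors Ms4a3 and Ctsg rose by 1.17 (adjusted p = 0.0110) and 1.09 (adjusted p = 0.0308). The chemokine receptor gene Cxcr2 and the receptor gene Csf3r fell by 1.45 (adjusted p = 0.0333) and 0.95 (adjusted p = 0.0296). The abundant granule and cytosol genes S100a9 and Ngp were called higher at 0.82 and 0.76 as deposited. After quantile normalisation they had changes of 0.09 (adjusted p = 0.658) and 0.13 (adjusted p = 0.541), and centring on the array median left Ctsg at 0.85 (adjusted p = 0.0533) and Ngp at 0.52 (adjusted p = 0.0560). As deposited, 49 genes with a mean log2 level above 15 had a median change of 0.37, with 16 called higher and 0 lower. Quantile normalisation gives every array the same distribution and so sets that median near 0 (-0.01), which leaves open whether the genes or the scale differed. Mpo, the peroxidase of early granules, had signals of 27460 ± 1198 and 40750 ± 5951 and did not pass (0.56, adjusted p = 0.0699), but did with pseudocount 64 (0.0414), an intensity trend (0.000971) and among genes above the median level (0.0127). With the block the 10 called genes had adjusted p from 0.0686 to 0.121.

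B cell genes were lower. Of 18 measured, 0 were called higher and 5 lower (0 and 11 adjusted over the list alone), and all 18 had a negative change, with a median of -0.91 (camera adjusted p = 4.59e-08; adjusted p = 0.246 with an estimated correlation; fry adjusted p = 0.0398). Cd79a, a signalling chain of the B cell receptor, went from 4389 ± 738 to 1345 ± 347 (log2 change -1.71, SE 0.24, adjusted p = 0.0149). Ms4a1, which encodes CD20, fell by 1.62, the coactivator gene Pou2af1 by 1.27 and Cd79b by 1.26, with adjusted p from 0.0391 to 0.0482, and with the block the 4 genes had adjusted p from 0.0521 to 0.0661. After quantile normalisation Pou2af1 and Cd79b did not pass (adjusted p = 0.0559 and 0.0522), and with pseudocount 1 neither these (0.0642 and 0.0611) nor Ms4a1 did (0.0538). Pou2af1 had an adjusted p of 0.0514 when genes were taken as the mean of their probe sets. Scaling to the poly-A controls raised the median of all genes to 0.96 and turned the B cell median to 0.05, so that relative to all genes it was -0.91 there and -1.01 as deposited.

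Of 16 erythroid genes, 0 were called in either direction, by limma over all genes or over the list alone. Their median was -0.38 and camera placed the list below the other genes (adjusted p = 0.00458), a call that was absent with an estimated correlation (adjusted p = 0.569), with fry (adjusted p = 0.273), among genes above the median level (adjusted p = 0.0630) and without endosteal array A (median -0.17, adjusted p = 0.0720). Hba-a1 could be measured alone only by a probe set near background (central mean 18.5 ± 22.4, log2 difference -0.20, adjusted p = 0.836). T and NK cell genes gave 0 calls among 13 (median -0.13, camera adjusted p = 0.133) and MHC class II and dendritic genes 0 among 12 (median -0.13, camera adjusted p = 0.0607), with 0 calls over either list alone. Without endosteal array A the T and NK cell list passed (median -0.35, adjusted p = 0.0326, over alternatives 0.0326 to 0.437). The MHC class II list passed with the mean of all probe sets (median -0.30, adjusted p = 0.0256), without central array A (median -0.26, adjusted p = 0.0300) and without endosteal array C (median -0.29, adjusted p = 0.0338, over alternatives 0.0256 to 0.269).

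Pathway genes were compared on the same arrays, again beside a muscle median of 5.32. Of 24 Wnt pathway genes, 10 were called higher and 0 lower (12 and 0 adjusted over the list alone), with a median of 0.79 (camera adjusted p = 0.000266; adjusted p = 0.163 with an estimated correlation). The genes that rose include the secreted inhibitors Wif1 and Sfrp1, by 4.20 and 1.70, the matricellular gene Ccn4, by 3.24 from a signal near background (23.3 ± 17.3; 2.21 to 4.04 over alternatives), and the receptor gene Fzd8, by 1.64 from a signal near background (20.8 ± 19.2). Fzd8 did not pass after quantile normalisation (1.32, adjusted p = 0.0960), after centring (1.41, adjusted p = 0.0544) or with pseudocount 1 (2.46, adjusted p = 0.0908). Its change ran from 0.88 to 2.46 over alternatives. The mean of the probe sets of Sfrp1 changed by 0.98 and did not pass (adjusted p = 0.0823). With the block Wif1 kept its call, and the other 3 had adjusted p from 0.0585 to 0.118. Of 25 TGF-beta and BMP pathway genes, 11 were higher and 2 lower (14 and 2 adjusted over the list alone), with a median of 0.91 (camera adjusted p = 0.000395; adjusted p = 0.182 with an estimated correlation). The ligand genes Bmp4, Tgfb3 and Bmp6 rose by 2.54, 2.43 and 2.23 and Bmp1, a procollagen protease, by 2.38. Tgfb3 and Bmp4 had central signals near background (9.91 ± 8.15 and 30.4 ± 19.35), and their changes ran from 1.32 to 3.70 and from 1.71 to 3.12 over alternatives. Bmp1 did not pass after quantile normalisation (adjusted p = 0.0511) or with pseudocount 1 (0.0502). Tgfbi fell by 0.77, and Tgfb1 by 1.12. With the block Tgfb3 kept its call and the others had adjusted p from 0.0521 to 0.0920. Among genes above the median level the list did not pass (median 0.27, adjusted p = 0.0932).

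Proliferation genes did not differ as a list. Of 24 cell cycle genes, 1 was called higher and 0 lower (0 and 0 adjusted over the list alone), with a median of 0.02 although camera pointed down (adjusted p = 0.723). The called gene, Pcna, the sliding clamp of DNA replication, was at 0.64 (adjusted p = 0.0446), and after quantile normalisation at 0.44 (adjusted p = 0.152) and after centring at 0.41 (adjusted p = 0.127), with an adjusted p of 0.0547 among means of probe sets and 0.0560 with pseudocount 1. Of 20 hypoxia and glycolysis genes, 1 was higher and 0 lower (4 and 0 adjusted over the list alone; median 0.38, camera adjusted p = 0.521). It was Ldha, lactate dehydrogenase A, at 0.54 (adjusted p = 0.04999, 0.0587 after quantile normalisation, 0.197 after centring, 0.0639 among means of probe sets and 0.0593 with pseudocount 1). Of 20 immediate early and stress genes, 1 was higher and 2 lower (1 and 3 adjusted over the list alone). Zfp36, which destabilises mRNA, and Ier2 fell by 1.05 and 0.82, and Hspb1, a small heat shock protein that muscle also expresses, rose by 2.59. Their median was 0.15 although camera pointed down (adjusted p = 0.347). Of 12 interferon response genes, 0 were higher and 1 lower (0 and 1 adjusted over the list alone), namely Irf7 at -1.21, with a median of -0.53. Camera placed that list below the other genes (adjusted p = 0.0146), a call that was absent with an estimated correlation (adjusted p = 0.467), with fry (adjusted p = 0.217), among genes above the median level (adjusted p = 0.0764) and without central array A (median -0.28, adjusted p = 0.177). With the block the named genes of these lists had adjusted p from 0.0620 to 0.133.

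Among called genes whose arrays did not overlap and whose central mean was above the median of all genes, the 10 largest decreases were, in order, Pot1b at -2.13, the interferon-induced Oas3 at -2.09, Fam169b at -2.05, Spib at -1.93, Fbxo10 at -1.81, Sowaha at -1.79, Wdtc1 at -1.78, Bach2 at -1.77, Adpgk at -1.73 and Pglyrp1 at -1.72. With pseudocount 1, Pot1b and Fam169b did not pass (adjusted p = 0.0662 and 0.0803). The mean of the probe sets of Adpgk changed by -0.77 and did not pass (adjusted p = 0.0907). Spib and Bach2 encode transcription factors of B lymphocytes, with signals of 6345 ± 1184 and 5774 ± 1373 in central and 1684 ± 554 and 1730 ± 669 in endosteal RNA (adjusted p = 0.0143 and 0.0256). Pglyrp1, a peptidoglycan-binding protein of neutrophil granules, went from 19820 ± 5631 to 5855 ± 366 (adjusted p = 0.0119). With the block the adjusted p of the 10 genes lay between 0.0521 and 0.105. Scaling arrays to the poly-A controls moved the median of all genes from 0.10 to 0.96. Of the 723 genes called lower, 469 then had a change above 0 and 254, among them these 10, a change below 0.

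By the study's own measure, the log2 ratio of mean signals, 4065 genes were at least 2-fold apart, 3207 higher and 858 lower in endosteal RNA. Of these, 1324 were also called by limma. With 16 added to each mean the number was 2460 (2020 higher, 440 lower), and among genes above the median level it was 653 (418 and 235). The split depended on scaling and on single arrays, with 2438 higher and 1597 lower after centring and 3032 and 1314 without endosteal B.

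Control transcripts on the arrays bear on all of these comparisons. The poly-A controls, bacterial transcripts added to the RNA before labelling, averaged 10.51 ± 0.19 on the log2 scale on central and 9.48 ± 0.06 on endosteal arrays, a change of -1.02 in which 24 of 24 probe sets were lower. The hybridisation controls, added after labelling, changed by -0.14 (12.53 ± 0.08 and 12.39 ± 0.12). In exact permutation tests, two-sided, both gave p = 0.1, the smallest that 3 against 3 arrays allow. The ratio of 3' to 5' signal, a measure of RNA integrity, was 0.25 ± 0.05 and 0.43 ± 0.04 on the log2 scale for beta-actin (exact p = 0.1), -0.23 ± 0.06 and -0.27 ± 0.10 for Gapdh (exact p = 0.6) and 2.19 ± 0.11 and 2.08 ± 0.11 for the transferrin receptor (exact p = 0.4).

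**Figure D3:**
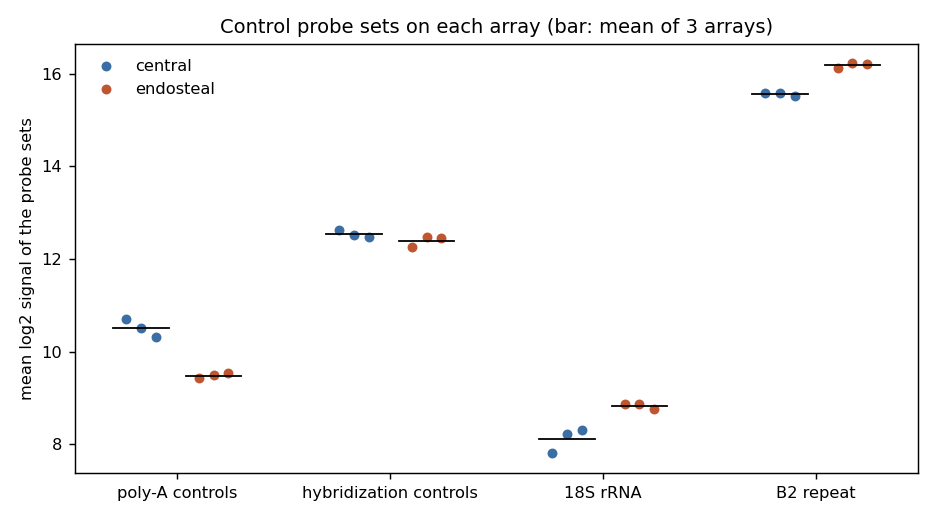
Mean log2 signal of 4 kinds of control probe set on the 3 central (blue) and 3 endosteal (red) arrays, with a bar at each mean. The poly-A controls were lower on endosteal arrays (means 10.51 and 9.48), the hybridisation controls changed by -0.14 (0.88 when scaled to the poly-A controls) with the highest endosteal array close to the lowest central one, and the 18S rRNA and B2 repeat probe sets were higher on all 3 endosteal arrays (18S means 8.12 and 8.83), of which B2 differed by 0.07 after quantile normalisation.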

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

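The tests on the poly-A controls and on the blood cell lists were chosen only after the result was seen, as was the count of muscle genes by letter, while the muscle shares and the splits of the arrays were set before.

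A few signals lay outside the comparisons between genes. The 18S rRNA control probe sets were 1.64-fold higher on endosteal arrays and the B2 repeat probe set 1.53-fold, in 3 of 3 arrays each (exact permutation p = 0.1, the smallest possible), although the B2 difference was 0.07 on the log2 scale after quantile normalisation. Of 10092 probe sets that name no single gene here, 162 were called higher and 119 lower in endosteal RNA when 45037 non-control probe sets were tested together with limma.

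Skeletal muscle genes held most of the largest increases in endosteal RNA, with endosteal signals of 16710, 15970 and 13560 for Myl1, Acta1 and Tnnc2, against 24.8, 146 and 33.2 on the same probe sets in central RNA. Of a second list of muscle genes, written down before its values were looked at, 79.3% were called higher (23 of 29, median 2.69), and among its members with no contractile role 93.3% (14 of 15), which argues against contractile genes being expressed alone by cells that line the bone. With the letter as a block 3 of 29 and 1 of 15 passed, while 29 of 29 and 15 of 15 were higher in every letter, with a median of at least 1.85 in each. The blocked test recovered 0% of simulated changes of 2 on the log2 scale, but the simulation had no letter effect and changed only 200 of 18193 genes. On the real arrays some changes near 2 passed with the block, such as Col11a2 at 2.18 (adjusted p = 0.0478). Others did not, such as Kcnk2 at 2.01 (adjusted p = 0.0630), so the simulation does not settle why calls were lost. Muscle tissue carried over with the bone is a candidate source, although the protocol rubs muscle off the femur; 3 of the 20 genes in the first list had a central mean above the median of all genes, and 0 stand in another list. There is no muscle sample, so the share of muscle RNA was not estimated, and a difference of the bone surface itself stays open as untested.

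The poly-A controls changed by -1.02 on the log2 scale, while the hybridisation controls changed by -0.14. The gap between both kinds of control changed by -0.88, where it ranged over at most 0.23 within a region, which argues against 1 scaling factor per array as the whole reason. More polyadenylated RNA per amount of total RNA, or a smaller amount of control added, could each give the change of -1.02. They cannot be told apart, because the amount added is not given in the sources used here. With arrays scaled to these controls, 10529 genes were called higher and 47 lower.

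Megakaryocyte and B cell genes moved apart, with medians of 1.25 and -0.91. These were the highest and lowest medians of the blood cell lists, so a wide gap between them was likely in advance. The gap between the lists changed by 2.31, and its lowest endosteal value exceeded its highest central value by 1.61, where it ranged over at most 0.79 within a region, which argues against dilution by RNA of bone, vessel and muscle as the whole reason. After quantile normalisation the gap was 2.32 (1.58 between the regions' nearest arrays, 0.92 at most within a region), which argues against a trend of the change with signal level. Stress of the central cells between flushing and lysis stays open and cannot be told apart from region, since only the central cells were held in suspension and 10% of immediate early and stress genes (2 of 20) were called lower in endosteal RNA. A different mix of blood cells in the regions also stays open, as untested.

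With 3 arrays against 3 there are 10 splits of the arrays, too few for a share under 0.05. For genes the real split, 1 of 10, called 2132, and the highest of the others 0. Every other split mixes the regions in both groups, so the region difference widens the spread within groups and few calls were bound to follow. Part of that difference also remains between the mixed groups, so neither their gene nor their list counts give a chance level. For lists the real split, again 1 of 10, called 16, and the highest of the others, which sets central A, central B and endosteal C against the rest, called 15. It is among the 4 splits that part all 3 letters, where the other 3 called 0 genes each and 15, 6 and 0 lists.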

How the results depend on the processing

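Scaling to the poly-A controls and the random block were chosen after the data were seen, the other alternatives before. With the letter as a block, limma called 85 genes higher and 0 lower (1899 lower at an unadjusted p under 0.05). A 1.5-fold minimum gave 370 and 18, an intensity trend with a robust prior 2225 and 1735, poly-A scaling 10529 and 47, and leaving out 1 array 502 to 890 and 89 to 297. Genes lower numbered 1106 with pseudocount 64, 1638 with median centring and 1722 among the 9096 genes above the median level, where genes higher stayed within 1.5 times. The remaining alternatives kept both counts within 1.5 times, from 1085 to 1668 and 497 to 941. Of the genes called higher as deposited, 480 to 746 remained when 1 array was left out, and of those called lower 78 to 227. The median change of all genes was 0.10 as deposited, -0.01 after quantile normalisation, -0.14 after centring and 0.96 after poly-A scaling. Genes 2-fold apart by the ratio of means numbered 2460 with 16 added, 653 above the median level and 4110 to 4609 without 1 array, of which 876 to 1314 were lower, and 4035 after centring, of which 1597 were lower, against 858 as deposited. Lists called were 16, and 0 with an estimated correlation (lowest adjusted p = 0.147), against 12 to 17 under the other alternatives run on lists. Leaving out an array leaves fewer samples and a level filter fewer genes; the cause of the other shifts was not tested. Of 108 named genes, the block ended 81 calls, the 1.5-fold minimum 49, unmoderated statistics 23, the mean of probe sets 14, pseudocount 1 also 14, quantile normalisation 9, centring 6 and leaving out 1 array 26 to 49. Direction was kept under these except for Hba-a1, which did not pass in any alternative and ran from -0.52 to 0.30 when 1 array was left out, with 0.30 without central C (adjusted p = 0.677, over alternatives 0.550 to 1). Signals near 16 limit what low genes can show, and saturation was not tested.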

Other observations

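All tests in this part were chosen after the data were seen, on families of genes taken by symbol and on globin probe sets.

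Of 37 families tested with camera at the preset correlation, 9 passed, and with an estimated correlation 0 did (adjusted p = 0.213 to 0.321 for the 9). Collagens led, with 22 of 42 called higher and 0 lower and a median of 1.61. Mitochondrial ribosomal proteins had 14 of 76 higher and 0 lower (median 0.42), subunits of respiratory complex I 9 of 34 and 0 (median 0.47) and ATP synthase subunits 7 of 17 and 0 (median 0.41). After centring on the array median these 3 medians were 0.18, 0.23 and 0.18, and after quantile normalisation they were 0.44, 0.49 and 0.39. Mrps28, Ndufc1 and Atp5g1 rose by 1.02, 0.89 and 0.97 (adjusted p = 0.0211, 0.0159 and 0.0175). Translation initiation factors did not pass, with 2 of 47 higher and 2 lower (median 0.12, camera adjusted p = 0.590). Cytosolic ribosomal proteins had 10 of 43 higher and 0 lower, and a median of 0.40 that was 0.17 both after quantile normalisation and after centring. The largest change among them was that of Rpl3l, known from striated muscle, from a signal near background (18.4 ± 18.2) to 404 ± 167 (log2 change 3.66, adjusted p = 0.0113).

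Heat shock protein genes had 6 of 29 higher and 0 lower (median 0.51, with 0.48 after quantile normalisation and 0.27 after centring). Among them were Hspb6 and Hspb7, which muscle expresses, at 2.08 and 1.65 (adjusted p = 0.0400 and 0.0101), and Hspa5 of the endoplasmic reticulum at 0.72 (adjusted p = 0.0377). Serpins had 8 of 40 higher and 0 lower (median 0.41; 0.14 after quantile normalisation and 0.17 after centring). Serpinh1, a chaperone of collagen, went from 123 ± 61.1 to 2162 ± 512 (log2 change 4.06, adjusted p = 0.00652), and Serping1, the C1 inhibitor, from 634 ± 211 to 4527 ± 594 (log2 change 2.84, adjusted p = 0.00541). Laminins had 3 of 10 higher and 0 lower (median 1.05), with Lama2, a chain of muscle basement membrane, at 2.59 from a central signal near background (adjusted p = 0.00415). Proteasome subunits had 5 of 39 higher and 0 lower (median 0.30, with 0.33 after quantile normalisation and 0.06 after centring). Among the family members named, Lama2 kept its call with the letter as a block (adjusted p = 0.0478) and the others did not. These values come from the arrays on which the muscle list had a median of 5.32.

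Globin probe sets that match several genes gave higher signals in endosteal RNA, whereas the erythroid list had a median of -0.38. The beta globin probe set had a signal of 37170 ± 1450 in central and 83170 ± 5028 in endosteal RNA (log2 change 1.16, limma adjusted p = 0.0185). The alpha globin probe sets changed by 1.11, 1.02 and 0.08 (adjusted p = 0.0232, 0.0325 and 0.823). After quantile normalisation the changes were 0.70 for beta and 0.25 for the mean of alpha globin. Saturation was not tested.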
